A study of Oryza sativa with 4 samples.

How the data were processed

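The data are log2 ratios from 4 arrays of 2 colours, each of s73 against Bahia wild type, with the dyes exchanged on 2 of them. Per the labels, 1 µg of total RNA of each sample was amplified and 10 µg of amplified RNA was coupled to dye. The submitters' processing notes name limma with no version. The scanner, the background correction and the normalization within arrays are not given in the sources used here.

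The deposited log2 ratios were already normalized and centred near 0. Neither the labels nor the value table states their direction. Per the file headers, the authors' deposited table holds a log2 fold change of wild type over s73 averaged over the 4 arrays, an average log2 intensity, a moderated t score, a p-value, an adjusted p-value and a log-odds score. For 41108 of the 43311 features the deposited fold change equalled the mean of the 4 columns within 0.0001, with no sign turned, so the columns were used as turned by the authors. For 2199 features it matched a mean with 1 or more spots left out, 1958 of these spots on replicate 3, and 4 features had no deposited value. A limma refit with a dye term and these spots left out gave t scores that correlated with the deposited ones at 0.999998, against 0.890 for a fit with no dye term. The header calls the deposited adjusted p-value a Bonferroni value, but the values follow Benjamini-Hochberg steps over 46131 features. The correlations among arrays, the other criterion fixed for the direction, were negative between dye orientations. By themselves they would also allow columns that had never been turned, so the direction rests on the deposited table.

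Of the features, 38641 named 1 locus of TIGR release 4, 878 several and 3792 none. Features of 1 locus were averaged per array, and the others were kept apart, which gave 41142 genes including 36472 loci. The files pair features with loci and not with gene symbols or descriptions. Symbols came from 98 pairs of symbol and locus in 8 lists, written from general knowledge before the data were examined, and 93 of these genes were measured. Of these symbols 53 were found once in the RefSeq gene table, 52 of them on the chromosome of the locus, and all 180 pairs of such genes on 1 chromosome stood in the same order. FC1 was the exception, as that table gives the name to a gene on chromosome 4, so FC1 here stands on the written pair alone. So do the 45 symbols not found once, among them OsPIL11, OsPIL12, OsPIL13, HY5L3, Ehd1, Ghd7, OsCO3, FKF1, GA2ox3, GA3ox2 and PR1b. Keyword lists could not be used, since the files hold no descriptions. Coordinates are not given, because the table is of another assembly.

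The fit was limma (version 3.58.1, R version 4.3.3), lmFit and eBayes, of the ratio against 0 with an intercept alone, two-sided, with Benjamini-Hochberg adjustment at 0.05 over all genes with values on at least 3 arrays. In that fit the dye part of the ratio counts as residual spread. A fit with a dye term takes out every difference between replicates 1 and 3 and replicates 2 and 4. Its p-values could be too small if that difference lay in the plants or the labelling and not in the dye. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 8 lists, with fry and an estimated correlation beside it. On simulated ratios of 41142 genes with the real spread, the fit with no dye term recovered 85% of 100 genes changed by 1 and 96% of 100 genes changed by 2 on the log2 scale, with 14 false calls. The fit with the dye term recovered 85% and 94%, with 2 false calls. With no dye term the simulated noise was drawn independently for each array, while the real ratios held a part that followed the dye. The 85% and 96% are therefore not the power of that fit on the real arrays, where it called 0 genes.

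The genes named were chosen by a rule fixed before the data were examined. SE5 came first, then up to 12 called genes on each side, filled with the smallest p-values where too few passed. Every measured flowering-time gene was named except 1 that is not reported here, and from every other list the members that passed, or up to 2 that did not. As no gene passed with no dye term, all 12 loci on each side were filled in, and 2 loci of each side are printed beside those that carry a symbol. OsPIL11 and CHLG were named after their values were seen. The alternatives changed the dye term, the normalization, the filters, the averaging of probes, the variance model, the array weights, the test and the arrays included. Array weights and leaving out 1 array both unbalance the dye orientations, so a share of the dye part can enter the mean. Signal over background is not given in the files, so no gene could be called absent.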

Results

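Gene expression in the rice line s73, obtained with gamma rays at 250 Gy from the cultivar Bahia, was set against that of Bahia wild type on 4 arrays of 2 colours. The title of the series names PHOTOPERIOD SENSITIVITY5 (SE5), the heme oxygenase that makes the chromophore precursor of the phytochromes, and photoperiodic flowering. Plants aged 4 weeks had grown for 3 weeks under 12 h of light and 12 h of dark, then 1 week under long days of 14 h of light and 10 h of dark, and were harvested 1 h after lights on. Each array carried 1 biological replicate of each genotype. The s73 RNA, which the labels call mutant, was in Cy5 on replicates 1 and 3 and in Cy3 on replicates 2 and 4. Every array gave 43311 log2 ratios with no missing value, and the median ratio lay between -0.0039 and 0.0025. The number of arrays, 4, limits the precision of every value.

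The SE5 transcript (LOC_Os06g40080, chromosome 6) had the largest mean ratio of the 41142 genes. Its log2 ratio was -4.41, -3.06, -4.00 and -2.98 on replicates 1 to 4, a mean of -3.61 ± 0.71 (SD, n = 4), or 12.2-fold in size. Its mean log2 level was 11.92 in one genotype and 8.31 in the other, and the median log2 intensity of all genes was 6.76. The header of the authors' deposited table defines the ratio as wild type over s73, which makes a negative value higher in the RNA labelled s73. The files do not settle that direction, and the opposite definition would turn every direction given here, so genes are described as lying on the SE5 side (negative) or on the opposite side (positive). With limma and no dye term, SE5 had a Benjamini-Hochberg adjusted p of 0.142 (unadjusted p = 3.10e-05), so it did not pass 0.05 over all genes. With a dye term in the limma model the adjusted p was 0.0044. In the authors' deposited table, which follows the same model, it was 0.0022. An exact two-sided sign-flip test gave p = 0.125, the smallest that 4 arrays allow.

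**Figure D1:**
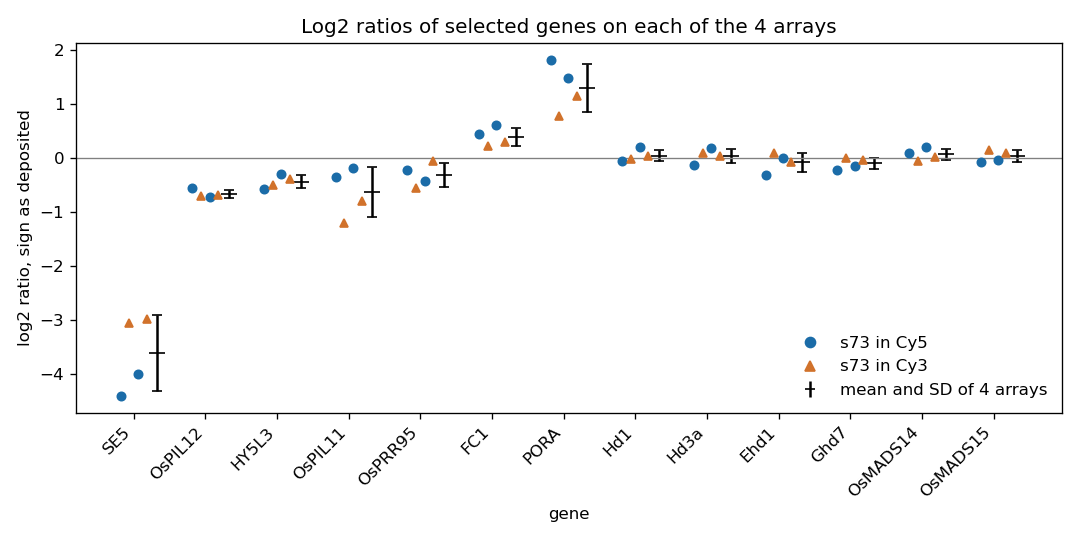
Log2 ratio, sign as deposited, of 13 genes (horizontal axis) on each of the 4 arrays: circles have s73 in Cy5, triangles have s73 in Cy3, and the black marks are the mean and SD of 4 arrays. SE5 lies between -4.41 and -2.98, PORA between 0.78 and 1.82, and the flowering genes from Hd1 to OsMADS15 lie near 0.

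Among genes of light signalling and tetrapyrrole synthesis, OsPIL12 and HY5L3 lay on the SE5 side, and PORA and FC1 on the opposite side, each with the same sign on all 4 arrays. OsPIL12 (LOC_Os03g43810, chromosome 3), a basic helix-loop-helix protein of the phytochrome-interacting type, had a mean log2 ratio of -0.66 ± 0.08 (SD, n = 4). HY5L3 (LOC_Os06g39960, chromosome 6), a relative of the light-response factor HY5, had -0.44 ± 0.12 (SD, n = 4). Its locus number is close to that of SE5 (LOC_Os06g40080), and whether its ratio is tied to that position was not tested. PORA (LOC_Os04g58200, chromosome 4), a light-dependent protochlorophyllide oxidoreductase, had 1.30 ± 0.44 (SD, n = 4). FC1 (LOC_Os05g29760, chromosome 5), a ferrochelatase, had 0.39 ± 0.17 (SD, n = 4). In the limma fit with no dye term their adjusted p-values over all genes were 0.142, 0.405, 0.387 and 0.601, in that order, so none passed. With the dye term OsPIL12 and PORA passed, each with a limma adjusted p of 0.0467, while HY5L3 and FC1 had 0.113 and 0.0924. These p-values rest on the spread within each dye orientation alone, and the orientations also held different plants.

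Of the 17 measured genes of phytochrome and light signalling, 0 passed over all genes. Adjusted over the list alone, 3 passed, all on the SE5 side: SE5, OsPIL12 and HY5L3. With an intensity trend in the limma variance model, the unadjusted p of OsPIL12 rose from 2.82e-05 to 0.0215. That of HY5L3 rose from 0.00068 to 0.0254, so the evidence for both depends on the variance model. OsPIL11 had a mean log2 ratio of -0.64 ± 0.46 (SD, n = 4). Its limma adjusted p over the list alone was 0.0655, and 0.0032 with the dye term, under which 4 genes passed over the list alone. The list as a whole had a camera p of 0.0430 and an adjusted p over the 8 lists of 0.202, with an adjusted p = 0.521 with an estimated correlation. Its mean ratio was -0.27 but its median was 0.02. In fry, which does not set the list against other genes, the directional adjusted p was 0.0117, and 0.0276 with SE5 taken out. The list without SE5 still held HY5L3, whose locus is close to that of SE5. With SE5 taken out the camera p was 0.278 and its adjusted p 0.849. Of the 20 measured genes of tetrapyrrole synthesis, which makes heme and chlorophyll, 0 passed over all genes. Adjusted over the list alone, 3 passed, SE5 on its side and PORA and FC1 on the other, and the list had a camera adjusted p of 0.799. With the intensity trend the unadjusted limma p was 0.0019 for PORA and 0.200 for FC1. With the dye term CHLG, a chlorophyll synthase, passed too over the list alone, with a mean log2 ratio of -0.26 ± 0.45 (SD, n = 4) and a limma adjusted p of 0.0102. Its sign differed between the dye orientations, with -0.64 where s73 was in Cy5 and 0.13 where it was in Cy3. Without 1 array the mean moved by over 1.5 times in 13 of the 16 light-signalling genes other than SE5, and turned sign in 5. For tetrapyrrole synthesis these counts were 16 of 19 and 11. Without 1 array the dye orientations no longer balance, so these moves also take in the dye part. OsPIL12, HY5L3, PORA and FC1 kept their sign.

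Of the 17 measured flowering-time genes, SE5 was the single one to pass when adjusted over the list alone, and 0 passed over all genes. The florigen gene Hd3a had a mean log2 ratio of 0.04 ± 0.13 (SD, n = 4). Among activators and repressors of flowering, Hd1 was at 0.04 ± 0.11, Ehd1 at -0.08 ± 0.17, Ghd7 at -0.10 ± 0.10, DTH8 at 0.01 ± 0.33 and RID1 at -0.05 ± 0.04 (SD, n = 4). Mean ratios of the MADS-box genes were 0.07 ± 0.11 for OsMADS14, 0.03 ± 0.11 for OsMADS15, 0.24 ± 0.52 for OsMADS18, 0.06 ± 0.13 for OsMADS50 and 0.26 ± 0.30 for OsMADS56 (SD, n = 4). Leaving out 1 array moved the mean by over 1.5 times in 14 of the 16 flowering-time genes other than SE5. In 9 of these it turned the sign, so their order has no meaning. The dye orientations then no longer balance, so the moves also take in the dye part. The remaining members, OsGI, OsCO3, Hd17 and FKF1, had -0.02, -0.02, -0.05 and -0.04. Of the 17 genes, 5 had an average log2 intensity below the median of all genes, 6.76. Among them were FKF1 at 6.58, OsMADS15 at 6.65, Hd1 at 6.67 and OsMADS14 at 6.69. Ghd7, RID1, Hd17 and OsGI lay just above it, at 6.79, 6.80, 6.80 and 6.85. Hd3a and Ehd1 were little higher, at 6.96 and 6.99. Signal over background is not known for any of these, so their ratios near 0 carry little information. The flowering list had a camera adjusted p of 0.799, with a mean ratio of -0.19 and a median of 0.01.

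Of the 13 measured clock genes, 0 passed over all genes and 0 adjusted over the list alone. OsPRR95, a pseudo-response regulator, had -0.31 ± 0.22 and OsPRR37 had -0.07 ± 0.05 (SD, n = 4). The clock list had a camera p of 0.0505 and an adjusted p of 0.202, with an adjusted p = 0.521 with an estimated correlation. Of the 16 measured gibberellin genes, 0 passed either way, with GA2ox3 at 0.29 ± 0.34 and GA3ox2 at -0.07 ± 0.07 (SD, n = 4). GA2ox3 was 0.13 without replicate 3. Of 6 genes of meristem and flower, 5 of root and 4 of senescence and pathogenesis, 0 passed over all genes or adjusted over the list alone. OSH1 and OSH71 of the shoot meristem had -0.05 and -0.07, OsNAR2.1 and Lsi2 of the root had -0.06 and -0.03, and SGR and PR1b of senescence and pathogenesis had -0.24 ± 0.41 and -0.81 ± 2.20 (SD, n = 4). PR1b rested on replicate 2, at -4.06, and was 0.27 without it. SGR rested on replicate 1, at -0.80, and was -0.06 without it. Leaving out 1 array, with the dyes again unbalanced, moved the mean by over 1.5 times in 10 of the 13 clock genes and 15 of the 16 gibberellin genes. It did so in all 6 meristem, 5 root and 4 senescence genes. The sign turned in 6 clock, 10 gibberellin, 4 meristem, 4 root and 3 senescence genes. The gibberellin, meristem, root and senescence lists each had a camera adjusted p of 0.799. The gibberellin list had a mean of 0.01 and a median of -0.0026, the meristem list a mean of -0.01 and a median of 0.0040, and the senescence list a mean of -0.17 and a median of -0.09.

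Over all 41142 genes, limma with no dye term called 0 genes at an adjusted p of 0.05, and 1703 had an unadjusted p under 0.05, 863 positive and 840 negative, where chance alone would give 2057. The plain one-sample test on the same ratios also called 0, and gave 1692 genes with an unadjusted p under 0.05. In limma this count was 3605 with the dye term and 3946 with array weights, both above 2057. The shortfall against chance thus depends on the fit. With the dye term limma called 54 genes, 30 positive and 24 negative, of which 44 had the same sign on all 4 arrays and 13 exceeded 1 in size. In 26 of the 54 the mean of 1 dye orientation was under 0.25 of that of the other in size, so the same sign on all 4 arrays does not show equal ratios. The authors' deposited table held 133 features with an adjusted p under 0.05, 71 positive and 62 negative. These stood for 132 genes, which included all 54 called with the dye term, each with the same sign. As that table follows the same dye-term model on the same arrays, the overlap is no independent support. Genes without a symbol are known here by locus alone. On the positive side the smallest p-values belonged to LOC_Os11g05290, at 0.93 ± 0.04, and LOC_Os05g44200, at 1.66 ± 0.19 (SD, n = 4). On the SE5 side they belonged to LOC_Os01g46720, at -0.94 ± 0.08, and LOC_Os06g06050, at -0.90 ± 0.10 (SD, n = 4). None of these 4 loci passed in the planned limma fit with no dye term. With array weights and no dye term all 4 passed, as did SE5 and OsPIL12, with limma adjusted p-values from 0.0286 to 0.0485. The weighted fit did not balance the dye orientations. In it the SE5 mean moved from -3.61 to -3.22, towards its -3.02 on the arrays with s73 in Cy3. Dye bias may thus enter these p-values and the count of 3946. The 12 loci with the smallest p on each side all had the same sign on the 4 arrays, with sizes from 0.44 to 1.66 on the positive side and from 0.50 to 3.61 on the SE5 side.

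Arrays correlated above 0 within a dye orientation and below 0 between orientations. Across genes, which are not independent replicates, Pearson's r was 0.438 between replicates 1 and 3 and 0.661 between replicates 2 and 4. The 4 pairs of opposite orientation had r between -0.253 and -0.150. The part of the ratio that followed the dye had 1.67 times the variance of the mean over the 4 arrays. With the dye sign as the tested coefficient, limma called 1020 genes, 402 positive and 618 negative. SE5 and PORA kept their sign in both orientations, with SE5 at -4.21 and -3.02 and PORA at 1.64 and 0.96.

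**Figure D2:**
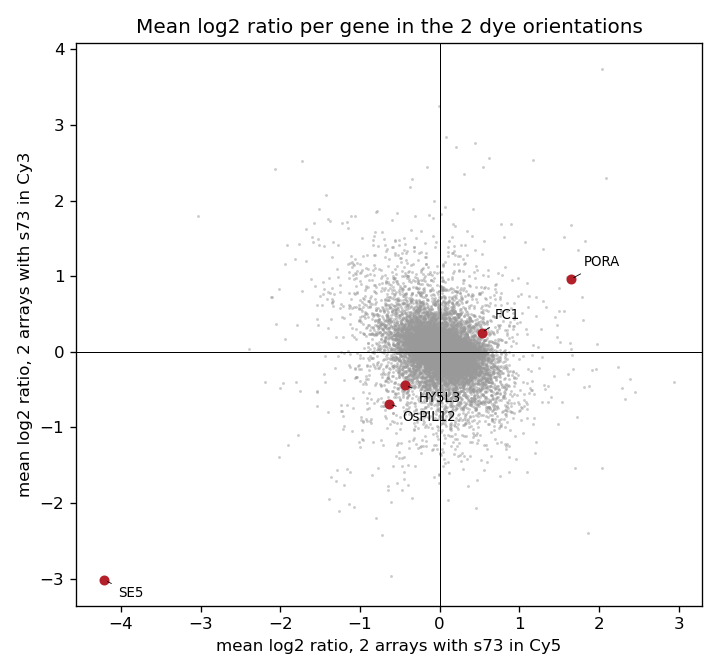
Mean log2 ratio of each gene on the 2 arrays with s73 in Cy5 (horizontal axis) against that on the 2 arrays with s73 in Cy3 (vertical axis), 1 grey point per gene, with 5 genes in red. SE5 stands alone at -4.21 and -3.02, and PORA lies on the opposite side at 1.64 and 0.96.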

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

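All weighing of explanations in this part was chosen after the result was seen. Among 97 genes and loci tested for an array far from the other 3, 3 stood out, where chance alone gives about 4.85. CHLI, a subunit of magnesium chelatase, had a log2 ratio of 5.51 on replicate 3, and the other arrays lay between -0.55 and 0.36. PBZ1, a pathogenesis-related gene, had 1.503 on replicate 1, and the others lay between -0.16 and -0.05. OsPIL13 had -0.0396 on replicate 4, and the others lay between -0.0066 and -0.0049, a gap of no size beside the spread of most genes.

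By the header's definition SE5 would be higher in the RNA labelled s73. Columns left unturned in 1 dye orientation would give SE5 opposite signs, but it was negative and over 1 in size on 4 of 4 arrays. If the mean held dye bias and no genotype ratio, SE5 would have no special place, yet the share of genes with a mean as large was 2.43e-05. A header that names the ratio the wrong way round may be the reason. PORA, which light signals through phytochrome are known to lower in other plants, lay on the opposite side at 1.30, but 1 gene seen beforehand decides nothing, so the direction stays open.

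Arrays of opposite dye correlated below 0. Of genes over 1 in size on all 4 arrays, 13 had signs that follow the dye and 8 had the same sign throughout, where the other sign patterns gave 0, so dye bias of single genes could account for the split. Plants or labelling days that differed between replicates 1 and 3 and replicates 2 and 4 could account for it too. The lowest r of a pair of like dye was 0.438, and no label gives days or plants, so this and the dye cannot be told apart. A biological difference between the plants of these pairs was not tested.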

How the results depend on the processing

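Spots left out after the authors, columns turned by the dye labels, and lists without SE5 were chosen after seeing the data. The count of 0 genes became 54 with the dye term and 13 with array weights, and the authors' deposited table held 133 features (132 genes). It became 4 with the authors' left-out spots missing, 121 with the dye term as well, and 260 with columns turned by the dye labels. It stayed at 0 under the other settings, from 0 to 0 without 1 array, where 1385 was the lowest count at an unadjusted p under 0.05. The cause was not tested except for the dye term, which takes the dye part out of the residual. With it goes any difference in plants or labelling between the dye orientations. The 8 ways of turning the 4 arrays are too few for a share under 0.05. With a real count of 0 they test nothing. The highest other, 260, is the one that follows the dye, which points to a structure of the arrays. SE5 kept its sign in all 19 alternatives and passed in 4. It was at -3.61 with the dye term, in the authors' table, and with spots left out and the dye term. These settings share 1 model and the same arrays, so they are not independent. With array weights, which unbalance the dyes, SE5 was at -3.22. Its adjusted p over all 19 alternatives ranged from 0.0022 to 0.998, and its mean from -3.82 to -3.35 without 1 array. Turned by the dye labels it was -0.59. In fry the light-signalling list passed with adjusted p = 0.0117 (directional), 0.00018 (mixed) and 0.0276 (SE5 taken out), the flowering list with 0.0027 and the tetrapyrrole list with 0.0131 (both mixed). With SE5 taken out, the mixed fry test of these last 2 lists gave adjusted p-values of 0.831 and 0.332. For the light-signalling list, which still held HY5L3, it gave 0.00039. Of 37 other named genes and loci 31 stayed on their side of the threshold throughout, and the other 6, OsPIL12, PORA and 4 unnamed loci, passed in some settings. With Spearman the mean correlation of like-dye pairs moved from 0.550 to 0.387. Without the intercept the dye was called in 260 genes against 1020. That fit, the columns turned by the dye labels and the turning that follows the dye are the same, so 260 is 1 result. Filters on missing values removed no gene, as no value is missing. Each ratio pairs 1 s73 RNA with 1 wild-type RNA, so the test against 0 was itself the paired analysis, and no other pairing was available. Signal over background was not given and limits the dim flowering genes.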

Other observations

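All tests in this part were chosen after the result was seen. On replicates 2 and 4, 8 of 20 neighbouring loci on chromosome 6 had ratios over 0.5 in size with the same sign on both arrays. Of these, 5 were positive, with means from 0.96 to 1.39 there and from -0.19 to 0.15 on replicates 1 and 3. The other 3 were negative there and followed the dye, with medians of -0.65 on replicates 2 and 4 and 0.81 on replicates 1 and 3. The window ends 30 measured loci before Hd3a, and lies 1872 measured loci from SE5. A wider window of 40 loci held 9 such loci and ended at LOC_Os06g06050, named above for its small p-value. Whether that locus belongs with the block was not tested.

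Chance order of the loci, all treated alike, is argued against for either direction. The permutation p was 0.002 from 1000 shuffles, with an adjusted p of 0.036 over 18 scans. In the window of 20, the loci over 0.5 in size had average log2 intensities from 7.25 to 12.09, where the median of all genes was 6.76. The shuffles did not match loci on intensity, so a grouping of brighter loci was not tested. For positive ratios alone chance order stays open, with a permutation p of 0.123. Dye bias of single probes stays open too. The median size of the 5 positive loci on replicates 1 and 3 was 0.0888 of that on replicates 2 and 4, but they were picked for that pattern, and the other 3 loci followed the dye. No biological explanation was tested.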
